A study of Mus musculus with 76 samples.

How the data were processed

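Single neurons were sampled by Patch-seq, in which the contents of a cell are drawn into a patch pipette in a brain slice, copied into a Nextera XT library and sequenced. The labels describe 76 such cells from dorsal CA1 of postnatal day 4 mice, each one GEO sample, with the genotype (GPHN WT or S268/270A, called Mut), the sex and a mark for contamination. No animal, litter, slice or batch is named. The electrophysiological recordings made from the cells were not used here.

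Per the labels the authors quantified the reads with kallisto on GRCm38, with no version stated. The deposited count tables hold expected counts per gene symbol, which are not whole numbers, once for all cells before a quality filter and once after it. The deposited normalized table holds TPM, a length-scaled transcript abundance, checked by the sum of each column and by its ratio to the counts. The criterion of the authors' quality filter and the basis of the contamination mark are not stated. Cells of other samples in the tables, 52 columns before and 44 after the filter, were not used here. The tables have 35825 gene symbols, of which 35338 matched the GENCODE M21 annotation and 487 did not. Xist, Tsix, Jpx, Ftx and Malat1 were not analysed here, since the tables have no value under these symbols.

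The authors kept 67 of the 76 cells. The 62 kept cells without a contamination mark were summed into 4 libraries, WT female (9 cells), WT male (19), Mut female (19) and Mut male (15), with the counts rounded after summing. Because no animal is named, cells were not treated as replicates and each group is 1 summed library. Cell numbers in the text are numbers within a group in the order of the labels. The cells hold 2946456 to 12070780 counts (median 6353179), and the sums hold 61543135 (WT female), 120682125 (WT male), 117701842 (Mut female) and 112199121 (Mut male). Exact Poisson intervals at 95% are given for summed counts. PCR reads without molecular identifiers are not independent molecules, and cells of 1 animal are not independent, so intervals and floors cover counting error only. A group without a read was given a floor of 3 counts.

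Genotype and sex were tested with edgeR 4.0.16 (quasi-likelihood F-test, glmQLFit and glmQLFTest, not robust) on the 4 sums, in 1 fit with sex and genotype as terms and 1 residual degree of freedom per gene. Genes were filtered with filterByExpr by genotype (minimum count 10), which left 16435 genes, and libraries were scaled with TMM (factors 0.865, 1.09, 1.04 and 1.02 in the order above). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.958 and the prior degrees of freedom were 3.6. The fit was tested on simulated data of the same genes with 200 changed genes. At a coefficient of variation of 0.96 it recovered 0% of changes of 4-fold and of 16-fold, with the right sign in 89% and 98%, and at 0.1 it recovered 100% of both, with 14 and 11 false calls. Within a sex, between the sexes of a genotype and for contaminated cells no test was made, since each group is 1 sum; the value given is the log2 ratio of TMM-scaled CPM, the edgeR unit of counts scaled to a common library size, with a pseudocount of 1 CPM. Values for contaminated cells come from a scaling over 6 sums, so the CPM of a WT male gene can differ slightly from that in the other comparisons. Fold changes are Mut over WT, or male over female.

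The 36 gene lists, the groups, the tests and the rule for named genes were fixed before the data were examined. For genotype over both sexes the rule takes up to 10 genes per direction, first those past the threshold and then those of smallest p that moved the same way in both sexes. For the untested comparisons it takes the 10 genes per direction (5 for sex within a genotype) of largest log2 ratio among genes at 25 CPM or more in the higher group, with at least 1 count in 50% of its cells and a median over cells moving the same way; Gm and Rik names were passed over. Gphn and up to 4 members of each list were named besides. A few genes that these rules take are not reported here. The count of 1 proved a low bar, because values of 1 to 9 reads were common: among 10096 genes that reached 1000 reads in some cell, 17.3% of values were 0, 33.4% were 1 to 9 reads, 14.0% were 10 to 99 and 35.3% were 100 or more. Cells carrying a gene are therefore counted at 10 CPM or more, a limit chosen after the data were seen. Gene lists were tested with fry (limma 3.58.1) on log CPM (prior count 2), whose directional p tests whether members move on balance one way and whose mixed p tests for change in either direction. Neither compares a list with other genes. Within each sex the median log2 ratio of a list was ranked among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries only.

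Alternatives fixed in advance were DESeq2 1.42.0, median-of-ratios scaling, library totals, no covariate, no filter and a filter on cells, cells thinned to 2946352 counts, cells before the quality filter, contaminated cells included, pseudocounts of 0.25 and 5 CPM, the authors' normalized table, and leaving out each sum and each cell. Added after the data were seen were leaving out 5 cells with 6 or more of 11 microglial markers, leaving out 8 cells with fewer than 5 markers of the medial ganglionic eminence (MGE), leaving out the genes Gm19220 and Lars2, leaving out the highest cell of a gene, and a split of the sums by neither genotype nor sex. Transcripts of Gm19220, Lars2, Gphn and the Y-linked genes were compared with all GENCODE M21 transcripts with BLAST 2.17.0. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.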

Results

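The cells were tdTomato-positive neurons of the hippocampal CA1 pyramidal layer, marked through Nkx2.1-Cre as descendants of the medial ganglionic eminence (MGE), the embryonic origin of parvalbumin and somatostatin interneurons. They came from newborn mice with wild-type gephyrin (WT) or with gephyrin whose serines 268 and 270 were replaced by alanine (Mut). Gephyrin, the product of Gphn, is the scaffold that holds GABA-A and glycine receptors at inhibitory synapses and is also an enzyme of molybdenum cofactor synthesis; the 2 serines are phosphorylation sites. The 62 cells compared were 9 WT female, 19 WT male, 19 Mut female and 15 Mut male cells. A further 5 WT cells, 1 female and 4 male, are marked in the labels as contaminated and were compared apart. A cell held a median of 6353179 counts, and 9057 to 13663 genes with at least 1 count. Each group is 1 sum of cells without replicates.

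Most cells carried the transcripts of MGE interneurons at 10 CPM or more. Lhx6, the transcription factor that specifies MGE interneurons, was found in 57 of the 62 cells, and the GABA-synthesizing enzymes Gad1 and Gad2 in 58 and 48. Npy was found in 54 cells, Tac1 in 30 and Sst in 21, while Pvalb, the calcium-binding protein that defines mature basket cells, was found in 1 cell. Transcripts of other cells were also present: Neurod6, a transcription factor of pyramidal neurons, in 31 cells, Slc17a7, their vesicular glutamate transporter, in 22, and the haemoglobin gene Hbb-bs in 43. The most abundant transcript was Gm19220, a processed pseudogene, with a median of 22757 CPM, followed by Lars2 (16264 CPM) and the tubulin gene Tuba1a (11730 CPM).

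Gphn itself (chromosome 12, 78226379 to 78684772 of GRCm38) was lower in the Mut sum of each sex. It stood at 164 CPM in WT females (95% interval 160 to 167, 8709 counts) and 98.6 CPM in Mut females (96.9 to 100.4, 12050 counts), a log2 ratio of -0.73. In males it stood at 112 CPM in WT (110 to 114, 14676 counts) and 57.8 CPM in Mut (56.4 to 59.2, 6605 counts), a log2 ratio of -0.94. Over both sexes the log2 fold change was -0.84 (SE 0.49, unadjusted p = 0.152 and adjusted p = 1 in edgeR). At 10 CPM or more, Gphn was found in 7 of 9 WT female, 12 of 19 WT male, 10 of 19 Mut female and 6 of 15 Mut male cells, with medians over cells of 32.5, 45.7, 31.3 and 8.33 CPM. WT female cell 8 held 75.8% of the Gphn counts of its sum; without it the female log2 ratio was 1.13 and the value over both sexes 0.10. The mutation changes 2 codons, so the level of this RNA does not check the genotype labels.

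**Figure D1:**
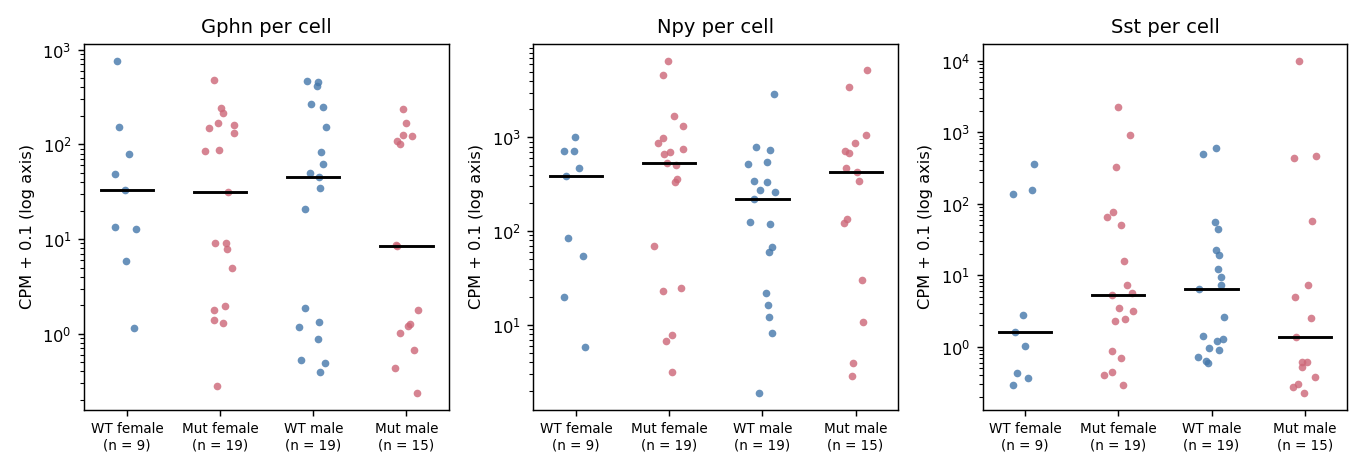
Gphn, Npy and Sst in each of the 62 cells (CPM + 0.1, log axis) by genotype and sex, with 1 point per cell and a line at the median of the cells. Median Npy was 534 CPM in Mut and 384 CPM in WT females and 427 and 222 CPM in males, while median Sst was 5.15 and 1.51 CPM in females and 1.25 and 6.27 CPM in males, and the highest Sst was 2287 CPM in Mut female cell 22 and 10062 CPM in Mut male cell 7.

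The comparison of genotypes over both sexes asked which genes separated Mut from WT interneurons. Npy, which encodes the inhibitory neuropeptide Y, stood at 1293 CPM in Mut and 410 CPM in WT females, and at 827 and 374 CPM in males (log2 fold change 1.40, SE 0.32, unadjusted p = 0.00902). Sst, encoding the peptide somatostatin that names a class of MGE interneurons, stood at 287 and 73.8 CPM in females and at 722 and 42.9 CPM in males (3.02, SE 0.68, p = 0.00818). Prox1, a transcription factor of interneurons from the caudal ganglionic eminence (CGE) and of dentate granule cells, stood at 51.0 and 35.0 CPM in Mut females and males against 0.0940 and 0.16 CPM in WT. Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 14704 CPM in Mut and 30017 CPM in WT females and at 9361 and 24923 CPM in males (-1.22, SE 0.22). None of these genes passed the test.

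The neuropeptide values differed in how many cells they rested on. Npy reached 10 CPM in 16 of 19 Mut female and 13 of 15 Mut male cells and in 8 of 9 and 17 of 19 WT cells, and without Mut female cell 22 its log2 fold change was 0.999. Sst reached 10 CPM in 7 Mut female, 4 Mut male, 3 WT female and 7 WT male cells. Mut male cell 7 held 93.0% and Mut female cell 22 held 74.4% of the Sst of their sums, and without Mut male cell 7 the log2 fold change was 1.15. The median Sst over cells was higher in Mut females than in WT females (5.15 and 1.51 CPM) and lower in Mut males than in WT males (1.25 and 6.27 CPM). Prox1 reached 10 CPM in 5 Mut female and 2 Mut male cells and in 0 of 28 WT cells, which allows a share of up to 10.7% of WT cells. Of these 7 cells, 5 also carried Lhx6, 6 carried Gad1 and 5 carried Npy. Without Mut male cell 12 the log2 ratio of Prox1 in males was 2.56 instead of 4.96. Npy lies on chromosome 6 (49822710 to 49829507), Sst on chromosome 16 (23889573 to 23890958) and Prox1 on chromosome 1 (190118035 to 190170714).

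Of the other genes named as higher in Mut, Rcn1, a calcium-binding protein of the endoplasmic reticulum, stood at 56.3 and 25.3 CPM in Mut females and males against 0.13 and 0.12 CPM in WT, and reached 10 CPM in 8 Mut cells (5 female, 3 male). Ptgs1, a cyclooxygenase, stood at 62.7 and 73.1 CPM against 0.19 and 1.82 CPM. Cdc7, a kinase of DNA replication, stood at 18.1 and 84.2 CPM against 0.36 and 5.31 CPM. Rpusd4 and Zfp945 lay between 22.7 and 30.0 CPM in the Mut sums and at 0.28 CPM or less in the WT sums. Bfsp1, a filament protein of the lens, rested on Mut male cell 7, with 42.6 CPM in that sum, 3.41 CPM in Mut females, 0.21 CPM in WT males and no read in WT females, where the floor of 3 counts is 0.0564 CPM. Il1a, the inflammatory cytokine interleukin 1 alpha, had the smallest p (0.00285), at 619 and 70.5 CPM against 101 and 14.96 CPM. Mut female cell 20, in which 10 of 11 microglial markers reached 10 CPM, held 99.2% of the Il1a of its sum, and without it the log2 fold change was -1.02 instead of 2.43.

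Among the genes lower in both Mut sums, Lars2 (chromosome 9, 123366927 to 123462666) reached 10 CPM in all 62 cells. Sox9, a transcription factor of glia and neural progenitors, stood at 17.3 and 5.44 CPM in Mut females and males against 342 and 28.2 CPM in WT, and Gab1, an adaptor of growth factor receptors, at 7.26 and 0.27 CPM against 128 and 13.6 CPM. WT female cell 7, which held 8222 CPM of astrocyte markers against at most 1282 CPM in the other WT female cells, moved both: without it the log2 fold changes were -0.82 for Sox9 (-3.34 with it) and -1.26 for Gab1 (-4.88 with it). Dhx40, a helicase, stood at 34.8 and 5.84 CPM against 193 and 52.5 CPM, and Arl6, a GTPase of cilia, at 21.9 and 7.20 CPM against 184 and 43.4 CPM. Zfp213, Rasl10a, Arhgap27 and Fank1 were at 0.13 CPM or less in both Mut sums and between 5.43 and 27.4 CPM in WT, each in 4 or fewer cells at 10 CPM. Of the reads in WT females, 1 cell held 95.1% for Zfp213 (cell 3), 98.7% for Rasl10a (cell 2), 98.5% for Arhgap27 (cell 6) and 99.3% for Fank1. In WT males the highest cell held 72.9%, 61.2%, 82.0% and 42.8%.

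No gene passed the edgeR test of genotype: 0 were higher and 0 lower at an adjusted p under 0.05 (lowest adjusted p 1), and 273 were higher and 302 lower at an unadjusted p under 0.05. A split of the same sums that follows neither genotype nor sex gave more genes at this unadjusted limit in edgeR, 378 in one direction and 324 in the other. DESeq2 called 367 genes higher and 299 lower in Mut, among them 16 of the 20 genes that the naming rule took, but called 481 and 264 for this split. The split sets WT females and Mut males against WT males and Mut females. Genes whose genotype difference is opposite in the sexes are called in it too, so it is not a comparison free of differences. It cannot tell how many of the DESeq2 calls are false.

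**Figure D2:**
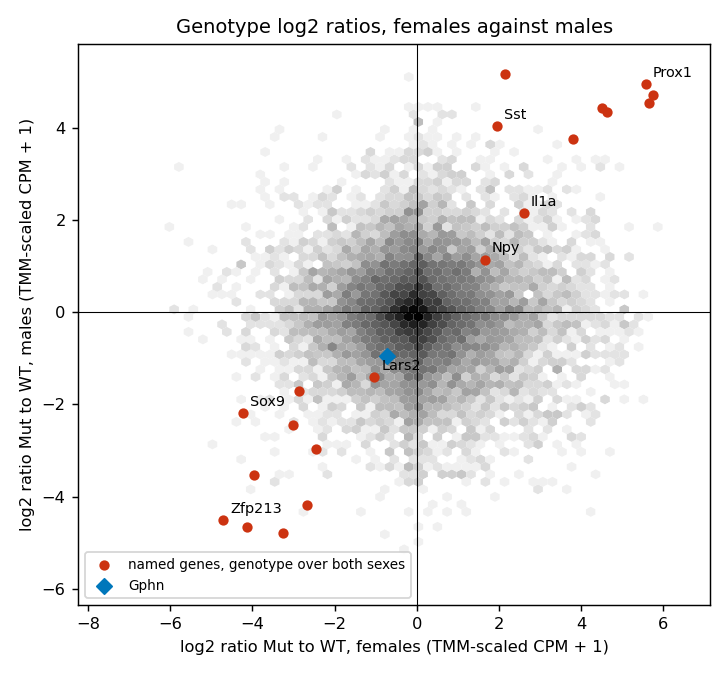
Log2 ratio Mut to WT of each gene in females (horizontal axis) and in males (vertical axis), as the density of all 16435 tested genes (darker for more genes), with the 20 genes that the naming rule took over both sexes in red and Gphn in blue. The ratios of the sexes were uncorrelated across genes (Pearson -0.0110), and the red genes lie in the corners because the naming rule asks for the same direction in both sexes.

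The fixed gene lists were compared by the direction of their members in both sexes. Of 643 list members, 271 in females and 238 in males changed the sign of their ratio when 1 cell was left out, as did 28 of the 72 list medians. At inhibitory synapses, the postsynaptic scaffold list had 4 members higher and 8 lower in both sexes and 4 opposite. Its median log2 ratios were -0.43 in females (0.06 without WT female cell 1) and -0.21 in males (-0.03 without WT male cell 6). Its lower members included Gphn, the glycine receptor subunit Glrb (-0.70 and -0.46) and Lhfpl4, which anchors GABA-A receptors (-0.38 and -0.75), while the adhesion protein Nlgn3 was higher (1.35 and 0.63). Of 12 GABA-A receptor subunits, 4 were higher in both sexes, among them Gabra5 (1.35 and 0.12), and 8 went opposite ways, among them Gabra2 (-2.14 and 1.06). Their median was 0.80 in males, above 98.9% of random lists, and -0.21 in females, or 0.05 with library totals. All 6 genes of GABA synthesis, loading and uptake went opposite ways, for example Gad1 (-0.37 and 0.26). Among 9 chloride cotransporters and their kinases, 4 were higher and 2 lower in both sexes: Slc12a5 (KCC2), which extrudes chloride, was higher (0.32 and 1.27) and Slc12a2 (NKCC1), which imports it, was lower (-1.64 and -3.58; 0.39 in females without WT female cell 3). Among 7 genes of the molybdenum cofactor pathway, 3 were lower and 0 higher in both sexes (Mocs2 -0.10 and -0.58), with a median of -1.10 in males. This male median was -0.29 without WT male cell 16 and -1.81 without Mut male cell 8. Of 16 kinases and phosphatases of gephyrin, 3 were lower, 2 higher and 11 opposite, with the calcineurin subunit Ppp3ca at -0.77 and -0.13. None of these lists passed fry; the scaffold list had a mixed p of 0.00405 (adjusted 0.146).

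Among receptors for glutamate, 7 of 14 AMPA receptor and auxiliary subunits were lower in both sexes and 2 higher (medians -0.39 and -0.24, fry p = 0.0714, adjusted 0.643); without WT male cell 16 the male median was 0.03. They included Gria2, which sets the calcium permeability of the receptor (-0.13 and -0.45), Gria3 (-0.10 and -0.85) and the auxiliary subunit Cnih2 (-0.65 and -0.22), whereas Gria1 went opposite ways (-0.99 and 0.15). Of 5 NMDA receptor subunits, 2 were higher in both sexes and 3 opposite (Grin1 2.09 and 0.19, Grin2b -0.67 and 0.27). Kainate receptor genes had 3 higher and 4 opposite (medians 0.95 and 0.12). Grik1 was at -0.86 and 1.06, or at 2.21 without WT female cell 9 and -0.20 without Mut male cell 7.

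Among ion channels, 9 of 15 voltage-gated calcium channel genes were lower in both sexes and 3 higher, including Cacna1h (-0.89 and -0.99), Cacna1d (-0.17 and -1.37) and the subunit Cacnb3 (-1.30 and -0.21; 0.20 in females without WT female cell 7). Their median fold change over both sexes was -0.79, lower than all but 0.36% of random lists, but fry gave p = 0.407. Of 22 voltage-gated potassium channel genes, 9 were lower, 6 higher and 7 opposite; Kcnd3, a channel of the A-type current, was at -3.02 and -3.22 (unadjusted p = 0.0221). The list of HCN and two-pore channels had 2 higher, 2 lower and 5 opposite. Of 8 sodium channel genes, 7 went opposite ways (Scn8a 0.09 and -0.51) and 1 was higher.

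Presynaptic and wiring genes were divided between the same and opposite directions in the sexes, as were all tested genes, of which 50.2% had the same sign in both. Of 25 genes of synaptic vesicle release 15 went opposite ways (Vamp2 -0.70 and 0.52, Snap25 -0.10 and 0.58), with 4 higher and 6 lower. Of 32 genes of synaptic adhesion 17 went opposite ways, 9 were higher and 6 lower (Cadm1 -0.31 and -0.74). Their median in males was 0.49, above 98.0% of random lists, and their fry p was 0.0562 (adjusted 0.643). Among 37 genes of migration and axon guidance, 8 were higher, 10 lower and 19 opposite; Nrp1, a semaphorin receptor, stood at 85.1 CPM in Mut and 336 CPM in WT females and at 53.6 and 96.5 CPM in males (unadjusted p = 0.049, not past the test), and the microtubule protein Dcx was at -1.34 and 0.36. Of 18 genes of developmental cell death, 4 were higher, 5 lower and 9 opposite (Pcdhgc4 -0.82 and -0.80).

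Activity-regulated genes had a median of -0.97 in females, lower than all but 0.08% of random lists, and of 0.22 in males; 8 of 21 were lower in both sexes, 2 higher and 11 opposite. Without WT female cell 2 the female median was -0.06, and without Mut male cell 7 the male one was -0.62. Their fry p over both sexes was 0.450, and the difference between the sexes was not tested. Examples are Fos (-0.97 and -0.36) and Egr1 (-0.27 and -0.38; 0.38 in females without WT female cell 2). The stress-induced Atf3 was at -2.71 and -1.33 (unadjusted p = 0.0379), but at 3.61 without WT female cell 7 and 0.41 without WT male cell 16. The heat shock and unfolded protein list had 6 higher, 7 lower and 5 opposite, with the chaperone partner Dnajb1 at 421 to 89.7 CPM in females and 145 to 63.7 CPM in males and Hspa8 at 0.01 and 0.33. In the mTOR pathway 11 of 14 genes went opposite ways (Mtor -2.20 and 0.36), 2 were higher and 1 lower. Mitochondrially encoded genes had 2 lower and 11 opposite (mt-Co3 -0.21 and 0.14), and the nuclear respiratory chain 17 higher, 16 lower and 45 opposite (Atp5b -0.55 and 0.22). Among 85 cytosolic ribosomal proteins 18 were higher, 28 lower and 39 opposite (medians -0.05 and -0.02; Rpl4 -0.41 and -0.25), and among 37 proteasome subunits 9 were higher, 6 lower and 22 opposite (Psmc2 1.39 and 0.78).

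None of the lists of interneuron classes passed fry after adjustment. Of 13 genes of the somatostatin lineage, 7 were higher in Mut in both sexes, 0 lower and 6 opposite, with medians of 1.73 in females (above 99.98% of random lists) and 0.58 in males (above 94.99%). Without Mut male cell 19 the male median was 0.11. Besides Sst and Npy, Pnoc, the precursor of nociceptin, stood at 81.4 and 195 CPM in Mut against 23.9 and 43.1 CPM in WT females and males, while Reln (23.04 to 267 and 59.1 to 39.99 CPM) and Calb1 (45.7 to 270 and 42.2 to 32.2 CPM) were higher in Mut females and lower in Mut males. Their fry p was 0.148, and the lowest p adjusted over the list was 0.0586. Genes of the parvalbumin lineage had a median of 1.33 in males, above every random list, and of -0.38 in females, with 3 higher, 1 lower and 6 opposite (fry p = 0.529, difference between the sexes not tested). Without Mut male cell 14 the male median was 0.84, and without WT female cell 1 the female median was 0.13. Tac1 was at -0.49 and 1.65 and the potassium channel Kcnc1 at -0.36 and 1.71. Of 16 genes of MGE identity, 11 went opposite ways, 3 were lower, among them Lhx6 (-0.27 and -0.43), and 2 were higher, among them Sox6, a factor of MGE interneuron maturation (19.9 to 86.9 and 13.8 to 65.1 CPM). The CGE list had 3 higher, 2 lower and 4 opposite, with Prox1 higher and the peptide gene Cck lower (634 to 121 CPM in females, 499 to 350 CPM in males); its median over both sexes was -0.57 while fry pointed up (p = 0.0149, adjusted 0.535).

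No list of markers of other cells passed fry after adjustment. Of 17 pyramidal neuron genes, 8 were lower in both sexes and 2 higher, with medians of -0.78 and -0.51, lower than all but 0.80% and 1.33% of random lists (fry p = 0.0419, adjusted 0.643); without WT male cell 14 the male median was 0.02. Nrgn, a calmodulin-binding protein, stood at 68.8 and 145 CPM in Mut against 183 and 277 CPM in WT, and Slc17a6, a vesicular glutamate transporter, at 1.36 and 2.95 CPM against 113 and 19.4 CPM (log2 ratio -5.59 in females, -2.02 without WT female cell 8). The more abundant Mpped1 went the other way, at 702 and 843 CPM in Mut against 519 and 616 CPM in WT (scaled over 6 sums). Astrocyte and radial glia genes had 2 higher, 2 lower and 9 opposite, with medians of 0.43 and -0.73 (Apoe -0.30 and -1.87, Sparcl1 1.47 and -0.78). Without WT female cell 7 the female median was 2.52 and Apoe in females was at 2.73. Without Mut male cell 1 the male median was -1.46. Oligodendrocyte genes had a median of 2.67 in females and -0.61 in males, with 1 higher and 7 opposite (Olig1 1.33 and -2.55). Without Mut female cell 21 the female median was 0.95. Microglial genes had medians of 1.43 and -0.48, with 2 higher, 3 lower and 6 opposite (C1qb 1.98 and 0.73). Without Mut female cell 20 the female median was -1.84 and C1qb was at -1.21. Without Mut male cell 18 the male median was -2.02 and C1qb in males was at -2.81. Of 8 endothelial and pericyte genes, 5 were lower and 2 higher (Pecam1 -0.45 and -0.66, Col4a1 0.72 and 0.82). Blood genes had medians of 0.78 and -3.08, with 1 lower and 4 opposite; Hba-a2 stood at 578 CPM in Mut and 336 CPM in WT females and at 111 and 948 CPM in males. Mut female cell 18, with 26898 CPM of blood genes against a median of 347 CPM over the Mut female and 530 CPM over the WT female cells, set the female direction: without it the female median was -0.19. Without WT male cell 20 the male median was -2.35.

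Over the 36 lists, fry gave 2 with an unadjusted p under 0.05 (CGE interneurons and pyramidal neurons) and 0 after adjustment; without sex in the fit, the mixed test of the AMPA and of the CGE list had an adjusted p of 0.0466. Adjusted over all genes, 0 members of any list passed, and adjusted over the list alone 1 did, Prox1 in the CGE list (0.0284). Scaling by library totals moved the median of genes at 25 CPM or more by 0.26 in females and -0.09 in males, and with it or with median-of-ratios scaling 12 of the 72 medians changed sign, all within 0.25 of 0 under TMM. These were the female medians of the lists for GABA-A receptors, GABA synthesis, molybdenum cofactor, potassium channels, HCN channels, adhesion, migration, heat shock, proteasome, ribosomal proteins and Y-linked genes, and the male median of ribosomal proteins. The median over both sexes and fry also differed in sign for chloride cotransporters, heat shock, microglia and genes that escape X inactivation.

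**Figure D3:**
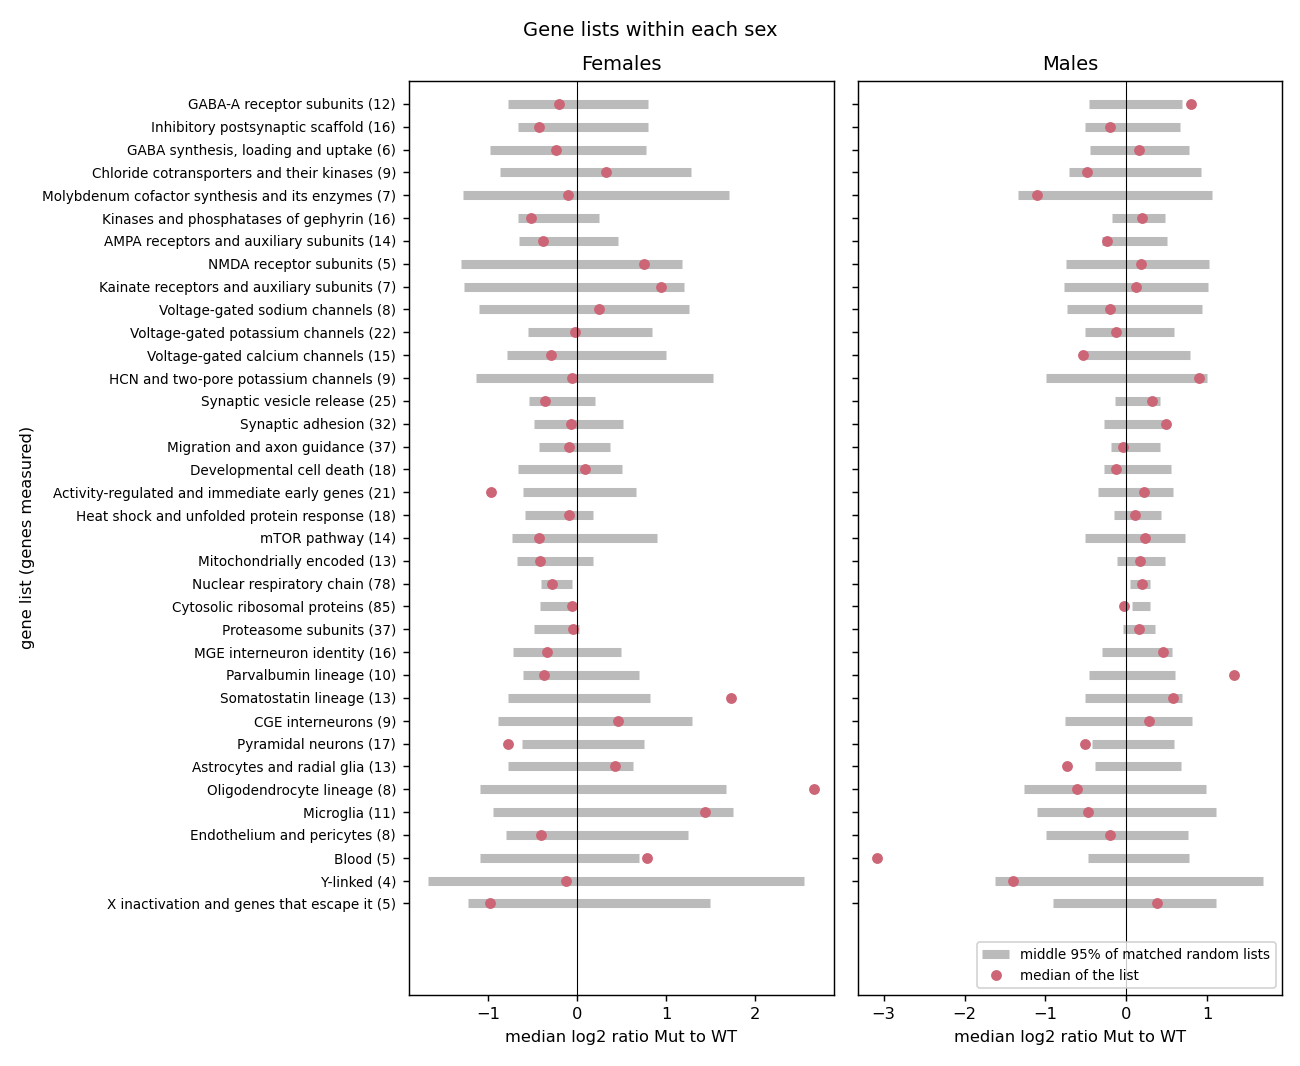
Median log2 ratio Mut to WT of each of the 36 gene lists (red points; number of genes in brackets) in females and in males, with grey bars for the middle 95% of 10000 random lists of like expression. Only the pyramidal neuron list lies outside the grey bar on the same side in both sexes (-0.78 and -0.51).

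In females alone the genes with the highest ratios were Sdc2, a cell surface proteoglycan (0.19 CPM in WT, 103 CPM in Mut, log2 ratio 6.45), Actr6, a subunit of a chromatin remodeller (0.23 and 91.4 CPM, 6.24), Cdk2ap1 (6.23), Nek6 (6.22), Yipf3 (6.15), Arpin (6.07), Ache, the acetylcholine-degrading enzyme (0.55 and 102 CPM, 6.07), Aldh9a1 (6.02), Tmem230 (5.92) and B3galnt1 (5.89). Except for Arpin, which was at 2.75 without Mut female cell 6, each of these rested on 4 to 9 Mut female cells at 10 CPM. The lowest ratios were those of Hsd17b7, an enzyme of steroid and cholesterol synthesis (-7.05), Bckdha, an enzyme of branched-chain amino acid breakdown (-6.96), Tex2 (140 and 0.24 CPM, -6.83) and Cdr1 (125 and 0.15 CPM, -6.77), found in 2 to 4 of 9 WT cells, and of Cyp7b1, Tmem177, Ccdc80, Pcdh20, Stk36 and Pcdhb9. Without WT female cell 8 the ratios were -5.97 for Hsd17b7, -5.11 for Bckdha and -5.54 for Cdr1, and without cell 9 the ratio was -4.68 for Tex2. The other 6 rested on single WT female cells: without cell 7 the ratios were -0.54 for Cyp7b1 (-7.54 with it), -0.79 for Tmem177, -0.51 for Ccdc80 and -0.30 for Pcdhb9, without cell 9 the ratio was -0.50 for Pcdh20, and without cell 8 it was -1.40 for Stk36. In males 4 of the 10 higher and 5 of the 10 lower genes moved the same way, and Sdc2 and Aldh9a1 were far lower in Mut males (-4.39 and -4.68).

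In males alone the highest ratios were those of Zfp707 (5.05), Prox1 (4.96), Plcd1, a phospholipase C (0.14 CPM in WT, 33.3 CPM in Mut, 4.91), Armc10 (1.85 and 79.3 CPM, 4.82), Stc1 (4.72), Gemin5 (4.67), Frg2f1 (4.66), Ddx28, a mitochondrial helicase (4.66), Edaradd (4.64) and Rcn1 (4.55). Ddx28 reached 10 CPM in 5 of 15 Mut male cells and the others in 2 to 4; Zfp707 was at 1.39 without Mut male cell 7 and Stc1 at 0.69 without cell 16. Plcd1 was at 2.23 and Frg2f1 at 2.36 without Mut male cell 5, Edaradd at 2.34 without cell 12, Armc10 at 2.88 and Gemin5 at 3.06 without cell 7, and Rcn1 at 3.53 and Ddx28 at 3.95 without cell 1. The lowest ratios included Pcp4, a calmodulin regulator (56.0 and 0.58 CPM, -5.18), Cdh8, a neuronal cadherin (73.3 and 0.74 CPM, -5.41), Ddx51 (-5.38), Cntrob (-5.16), Ezr (-5.05) and Tpd52l1 (-4.98), found in 3 to 6 of 19 WT male cells. Without WT male cell 16 the last 3 were at -3.73, -3.38 and -2.93, Cdh8 at -4.36 and Rnf122 (-5.76 with it) at -3.66, and without cell 6 Pcp4 was at -4.05. Prr5l (-5.53), the chaperone regulator Bag3 (-5.45) and Tgfbr2 (-5.23) rested on WT male cell 16, without which they were at -0.11, -0.69 and -1.02. In females 6 of the 10 higher and 2 of the 10 lower genes moved the same way, and Pcp4 (3.72) and Cdh8 (4.11) were higher in Mut.

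The ratios of the sexes were unrelated across the 16435 genes (Pearson -0.0110, Spearman -0.00137; genes are not independent replicates), and 50.2% of genes had the same sign in both. The median absolute log2 ratio was 0.767 in females and 0.637 in males, and 41.4% and 34.1% of genes differed by over 2-fold. Each ratio sets 1 sum against 1 sum, so differences between the cells sampled are not separated from genotype. The WT female sum also holds the fewest cells (9) and counts (61543135, against 112199121 to 120682125 in the other sums). The values therefore do not show a larger genotype effect in females. Among the 6484 genes at a mean of 25 CPM or more, Pearson was -0.00874 and 50.2% shared their sign. The male and the female log2 ratio of a gene differed by a median of 1.05 in absolute value. This difference of the genotype effect between the sexes could not be tested in a fit with sex and genotype. With 4 sums such a fit leaves no residual degree of freedom. The split that follows neither genotype nor sex sets the same contrast in a fit without genotype. There 0 genes passed in edgeR, while DESeq2 called 481 and 264. Genotype differences fall into the residual of that fit. The edgeR test of genotype on these sums recovered 0% of simulated changes at this spread, so the 0 says nothing about equal effects in the sexes.

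Sex was compared over both genotypes to check the sex labels and to find genes that differ between males and females. Eif2s3y, a translation factor on the Y chromosome, stood at 112 and 76.7 CPM in WT and Mut males and at 0.564 and 0.393 CPM in females (log2 fold change 7.62, SE 0.95, unadjusted p = 0.000721, adjusted 1). Ddx3y stood at 44.5 and 22.1 CPM in males against 1.05 and 1.83 CPM in females, and Uty at 24.0 and 6.04 CPM against 2.26 and 2.09 CPM. WT male cell 11 held 73.3% of the Uty of its sum, with a median of 1.83 CPM over the cells. Kdm5d stood at 34.6 and 7.39 CPM in males against 18.8 and 6.16 CPM in females, and reached 10 CPM in 8 of 19 and 5 of 15 male cells and in 5 of 9 and 5 of 19 female cells. Uty reached it in 5 male and 3 female cells. The transcripts of Eif2s3y, Ddx3y and Kdm5d matched those of their X-linked partners at 86.4%, 82.4% and 79.5% of bases in the longest match. Some part of them matched 3, 75 and 1627 other genes. Which of these matches bear on the reads in female cells was not tested. Eif2s3y or Ddx3y reached 10 CPM in 22 of 34 male cells and in 1 of 28 female cells, Mut female cell 18 (Ddx3y 47.0 CPM). Between genotypes the 4 Y-linked genes had a median of -1.40 in males (-0.61 without WT male cell 11), with 3 lower in both sexes and 1 opposite. Among genes that escape X inactivation, Kdm6a, a histone demethylase, was higher in Mut of both sexes (0.207 to 35.8 and 1.75 to 22.4 CPM), in a list with 2 higher, 1 lower and 2 opposite, while Ddx3x and Eif2s3x were highest in WT females (511 and 376 CPM). Mut female cell 15 held 57.8% and Mut male cell 12 held 68.0% of the Kdm6a of their sums, whose medians over cells were 0.36 and 0.46 CPM. Without these cells its log2 ratios were 3.81 (4.93 with it) in females and 1.72 (3.09) in males.

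Within WT the 5 named genes higher in males were Mb21d2 (log2 ratio 6.58), Wfs1, a protein of the endoplasmic reticulum that also marks CA1 pyramidal cells (0.77 and 145 CPM, 6.37), Tmtc4 (6.28), Eif2s3y (6.17) and Trim17 (6.004); without WT male cell 16 Wfs1 was at 4.69, and without cell 12 Trim17 was at 4.15. Those higher in females were Galnt4 (-7.42), Cyp7b1 (-7.23), Ddx28 (-7.10), Cyp4f16 (-6.75) and Nhlrc3 (-6.60). Without WT female cell 7 the first 3 were at -0.55, -0.23 and -3.71, without cell 8 Cyp4f16 was at -3.54, and without cell 9 Nhlrc3 was at -4.22. Within Mut, Cdr1 (5.93), Wdr17 (5.93), Eif2s3y (5.80), Mief2 (5.78) and Mapk15 (5.75) were higher in males; without Mut male cell 7 Cdr1 was at 4.56, Wdr17 at 4.80 and Mief2 at 4.91. Pcp4 (141 CPM in females, 0.58 CPM in males, -6.50), Sdc2 (-6.20), Il1b (-6.12), Gatc (-5.63) and Plekhf2 (-5.62) were higher in females; without Mut female cell 20 Il1b was at -0.27, and without cell 6 Plekhf2 was at -2.18. Over both genotypes edgeR called 0 genes higher and 0 lower in males (383 and 254 at an unadjusted p under 0.05), and DESeq2 called 445 and 260. The split by neither genotype nor sex gave 378 and 324 at the unadjusted limit in edgeR and 481 and 264 calls in DESeq2.

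The WT cells marked as contaminated were compared with the other WT male cells to learn which transcripts they carried. The 4 contaminated male cells were high in genes of innate immune cells: Tlr2, a receptor for bacterial lipoproteins (0.92 CPM in uncontaminated, 1011 CPM in contaminated cells, log2 ratio 9.05), Ifit1, an interferon-induced antiviral protein (1.05 and 1053 CPM, 9.01), Slfn2 (8.78), Lpcat2 (8.46), Il1a (15.1 and 5425 CPM, 8.40), Bcl2a1d (8.37), the chemokine Cxcl16 (8.33), Hilpda (8.31), Tnfrsf12a (8.31) and Tnfaip3 (8.30). Each of these 10 genes reached 10 CPM in 4 of 4 cells. All 11 microglial markers were higher, with a median log2 ratio of 6.59 that lay above every random list; examples are the complement gene C1qb (16.7 and 3462 CPM) and the growth factor receptor Csf1r (9.58 and 2165 CPM). Apoe, carried by astrocytes and activated microglia, stood at 639 and 26672 CPM, with 60658 CPM in contaminated cell 1 and a median of 7142 CPM over the 4 cells. Of 85 ribosomal protein genes 82 were higher (median 1.1996).

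Neuronal genes were lower in the contaminated male cells. Lhx6 stood at 91.0 CPM against 403 CPM and Gad1 at 109 CPM against 469 CPM. The list medians were -1.93 for GABA-A receptors, -2.17 for AMPA receptors, -1.46 for synaptic vesicle release, -1.52 for synaptic adhesion and -1.09 for migration and axon guidance. Neto1, an auxiliary subunit of kainate receptors, had the lowest ratio (101 and 0.70 CPM, -5.92), followed by Adnp2 (-5.89; -3.35 without WT male cell 16), Ppif (-5.75), Fbh1 (-5.72), Eif2d (-5.69), Camk4, a calcium-dependent kinase (-5.60; -3.87 without WT male cell 20), Pard6a (-5.39), the netrin receptor Unc5a (-5.30; -3.89 without WT male cell 20), Sh3gl3 (-5.25) and the haemoglobin gene Hba-a1 (569 and 14.2 CPM, -5.23). Blood genes had a median of -4.88. The single contaminated WT female cell also had 11 of 11 microglial markers at 10 CPM or more, with C1qb at 764 CPM and Lhx6 at 3.11 CPM. With 1 sum per group, no test was made.

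**Figure D4:**
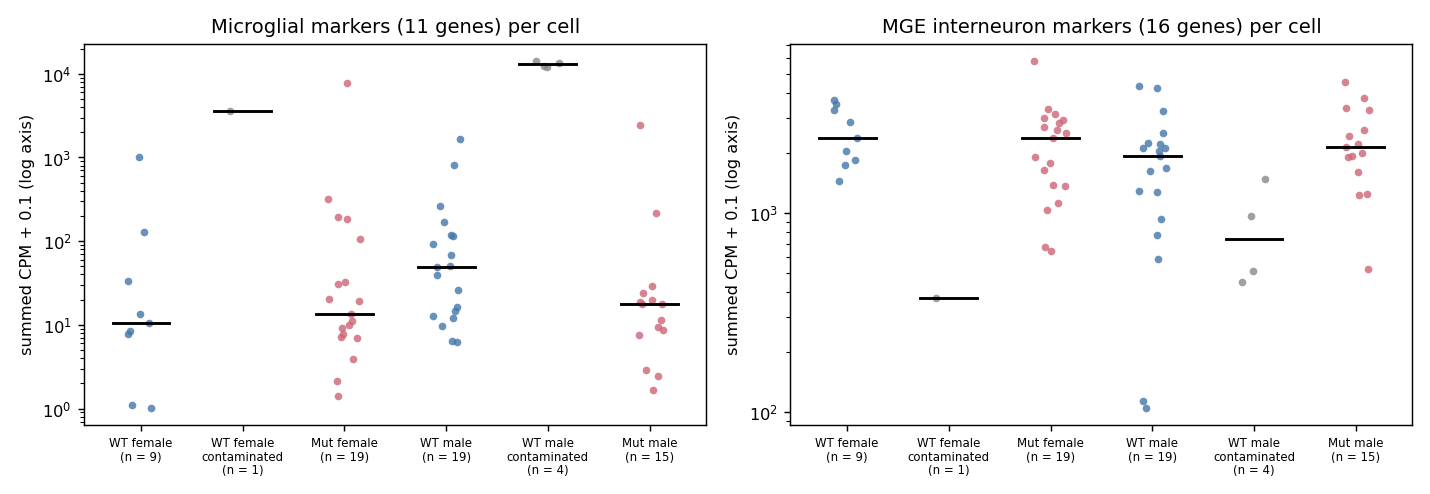
Summed CPM of 11 microglial markers (left) and 16 MGE interneuron markers (right) per cell (log axis, + 0.1), by group, with 1 point per cell and a line at the median. The 4 contaminated WT male cells sum to 11949 to 14090 CPM of microglial markers, and Mut female cell 20 is the uncontaminated cell nearest to them.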

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

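The tests of explanations given here were chosen after the results were seen, although thinning the cells and including the removed cells were alternatives fixed in advance. A cell was singled out when it stood apart from the other cells of its group in the gap to its neighbour, tested in groups of 4 to 10 cells. This happened in 8 of 40 combinations of a group and a measure. Chance gives about 1 in 20 (0.05) for normally distributed values; CPM of single cells is skewed, so more are to be expected and the count says nothing about chance.

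Gm19220 and Lars2, the most abundant transcripts, were lower in the Mut sums of both sexes, and cells removed by the authors' quality filter stood out in the same transcript. In 3 removed Mut cells Gm19220 took 47.7% (Mut female cell 4), 14.1% (Mut female cell 7) and 13.98% (Mut male cell 15) of the reads, against at most 11.6% in the cells used, and 8 of the 9 removed cells were at or above the median of the used cells. In the cells used, Gm19220 stood at 42814 CPM in WT and 23439 CPM in Mut females and at 34239 and 19759 CPM in males. The tables argue against the quality filter as the whole source of the genotype difference. With the removed cells included the log2 fold changes were -0.59 (Gm19220) and -1.18 (Lars2, -1.22 in the cells used). A part of the Gm19220 difference may still come from the filter. With thinned cells the log2 fold changes were -0.84 and -1.36, which argues against the greater weight of deeper cells in the sums. Thinning keeps the share of a gene within a cell on average, so it cannot exclude depth in any other way. The tables argue against a few cells as the source. The median share over cells was higher in WT than in Mut by 1.47 times in females and 2.05 times in males for Gm19220. For Lars2 it was higher by 1.91 and 2.14 times. A difference in RNA capture or quality between recording days or animals, and genotype itself, stay open and untested, because no animal or day is named. Whether the reads counted under Gm19220 and Lars2 come from these genes was not tested either.

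Il1a had the smallest p of genotype, and single cells with microglial markers stood apart. WT female cell 6, with 10 of 11 microglial markers at 10 CPM, summed to 1010 CPM of them against at most 129 CPM in the other WT female cells. The pattern is consistent with RNA of microglia taken up in single cells: without the 5 cells with 6 or more of these markers the log2 fold change of Il1a was -0.47 instead of 2.43. No biological explanation was tested for it.

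In WT females, cell 8 held 768 CPM of Gphn (others 1.05 to 153 CPM), cell 3 held 365 CPM of Sst (others up to 157 CPM), and cell 7 held 8222 CPM of astrocyte markers. Among the 4 contaminated WT male cells, cell 3 held 266 CPM of Sst and 1965 CPM of pyramidal neuron markers, and cell 1 held 63967 CPM of astrocyte markers, of which Apoe made up 60658 CPM, and 1455 CPM of oligodendrocyte markers. Blood genes went opposite ways in the sexes, with a median log2 ratio Mut to WT of 0.78 in females and -3.08 in males, both outside the middle 95% of random lists, but the female value rested on Mut female cell 18 with 26898 CPM of blood genes: without it the female median was -0.19. The median over cells was lower in Mut in both sexes (347 and 530 CPM in females, 197 and 367 CPM in males). This difference was not tested. Of the removed cells, Mut male cell 11 held 2351 CPM of Gphn, against at most 768 CPM in the cells used, and Mut male cell 9 held 5978 CPM of Lhx6, against at most 1628 CPM.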

How the results depend on the processing

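Leaving out the 5 cells with microglial markers, the 8 cells with few MGE markers, or Gm19220 and Lars2 was chosen after the data were seen; the other settings were fixed in advance. No paired analysis was possible because no animal is named, cell numbers only follow the order of the labels, and each group is a sum. With edgeR the 4 counts of genes past the threshold stayed at 0 under every other scaling, filter, covariate, set of cells and left-out cell or sum, in a design in which simulated changes were not recovered at this spread, so this says nothing about stability. With 1 sum in an arm, that sum is assumed to vary like the others. Tested named genes kept their direction and side of the threshold in 230 values outside the left-out cells and sums, and did not in 16 called by DESeq2 and 2 of Il1a. The 80 untested ratios of genes named for their size moved beyond their interval in 267 values and stayed within it in 506, and in 86 and 4090 with a cell left out. For ratios by genotype or sex, the 4090 include left-out cells of sums outside the ratio, which can move it only through the scaling. The 4090 therefore overstate how stable the ratios are. Without 1 cell Prr5l in males moved from -5.53 to -0.11 (WT male cell 16) and Cyp7b1 between WT sexes from -7.23 to -0.23 (WT female cell 7). Because these ratios were chosen as the largest, a kept sign says little. Depth limits the ratios of genes near 0 reads, which move with the pseudocount. For every change below the cause was not tested.

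DESeq2 called 367 genes higher and 299 lower in Mut, and 445 higher and 260 lower in males. With the contaminated cells included, Il1a was at -1.90, Gphn at -0.45 in females and -0.64 in males, and the correlation of the sexes at 0.0418. The median absolute log2 ratio was 0.696 in females and 0.658 in males, and the difference was 1.02. The difference here is the median over genes of the absolute difference between the male and the female log2 ratio. Without the cells with microglial markers, Il1a was at -0.47, Gphn at -0.82 in females and -0.46 in males, the median absolute ratio in females at 0.820 and the difference at 1.12. Without the cells with few MGE markers, Gphn was at -0.93 in females and the difference at 1.02. Before the quality filter, Gphn was at -0.81 in females and -0.59 in males, and the median absolute ratio in males at 0.620. With library totals Gphn was at -0.46 in females and -1.04 in males, and in the authors' table at -0.28 and -0.87. With thinned cells Gphn was at -0.59 in females, the median absolute ratio at 0.828 in females and 0.702 in males, and the difference at 1.12. A pseudocount of 5 CPM gave Gphn -0.89 in males. With it the median absolute ratio in females, that in males and the difference were 0.508, 0.420 and 0.693. With 0.25 CPM they were 0.9747, 0.797 and 1.32 (the difference was 1.05 as reported).

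With single cells or sums left out, Il1a ranged from -1.02 (without Mut female cell 20) to 4.53 (without the WT female sum), and Gphn over both sexes from -1.25 to 0.10 (without WT female cell 8). Gphn in females ranged from -1.07 to 1.13 (without WT female cell 8) and in males from -1.13 to -0.73. The correlation ranged from -0.0174 to -0.0004, and the median absolute ratio from 0.747 to 0.835 in females and from 0.633 to 0.672 in males. The median absolute difference between the male and the female ratio ranged from 1.03 to 1.12. The microglial median of the contaminated cells ranged from 6.37 to 7.69 (without WT male cell 6).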

Other observations

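The tests of Npy and Sst described here were chosen after the results were seen. Of the transcripts typical of CGE interneurons, at 10 CPM or more in the cells used, Nr2f2 was found in 9 of 62 cells, Calb2, a calcium-binding protein, in 8, Adarb2 in 7, Vip, a peptide of interneuron-selective cells, in 1 and Cck in 46. Nkx2-1, the transcription factor whose gene drives the Cre that switches the reporter on for good and which MGE interneurons of the cortex switch off as they mature, was found in 11 cells, Reln, a secreted protein of several interneuron classes, in 22, and Nos1, the neuronal nitric oxide synthase, in 10. Fos was found in 43 cells. Of the microglial markers, 6 or more of 11 reached 10 CPM in 5 of the cells used.

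Mut cells may hold more Npy than WT cells, while for Sst the sums and the medians over cells go different ways in males. For Npy the tables argue against 1 cell per sum as the whole source. Leaving out the highest cell of each sum gave a log2 ratio (CPM by library totals) of 1.57 in females and 1.27 in males. With all cells this ratio was 1.92 and 1.05. The male value rose because WT male cell 20 was left out too, which took the WT male sum from 407 to 236 CPM. Without Mut female cell 22 alone the log2 fold change was 0.999 instead of 1.40, so single cells carry part of the value. With thinned cells the log2 fold change was 1.28. Thinning keeps the share of a gene within a cell on average, so it cannot exclude depth. For Sst the median over cells was 5.15 CPM in Mut and 1.51 CPM in WT females, and 1.25 and 6.27 CPM in males. Leaving out the highest cell of each sum gave 1.15 in females and 0.96 in males, down from 2.22 and 3.98 (CPM by library totals). Thus 1 cell per sum accounts for part of the Sst value in each sex and the rest stays open. A larger share of Sst cells among Mut cells stays open, with 32.4% of 34 Mut cells at 10 CPM or more against 35.7% of 28 WT cells, too few cells to decide. Which animals and interneuron classes were patched in each group, and genotype itself, were not tested.

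Between 2 cells of a group the median correlation of expression was 0.598 in WT females, 0.615 in WT males, 0.594 in Mut females and 0.612 in Mut males. Mitochondrially encoded genes took a median of 1.22% of the counts of a cell (0.0660% to 5.55%). The authors removed 4 of 23 Mut female, 4 of 19 Mut male, 1 of 20 WT male and 0 of 9 WT female cells. The transcript of Gm19220 (803 nucleotides) matched no other annotated gene, and that of Lars2 matched 2, the longer match being 97 nucleotides at 94.8% of bases. This search covered annotated transcripts only. Whether ribosomal or mitochondrial RNA was counted under either gene could not be tested without the reads.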
